A study of Homo sapiens with 6 samples.

How the data were processed

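RNA-seq of polyadenylated RNA from C4-2 prostate cancer cells was analysed from the authors' table of expression values. The values are FPKM, fragments scaled to transcript length and to the number of mapped fragments, per the labels, which name the unit for the deposited table. The submitters' processing notes name TopHat2, Cuffdiff and the genome build hg19, without versions. The gene annotation, any filters and the normalization options are not given in the sources used here. The labels list 6 libraries: vehicle, GSK126, astemizole, scramble shRNA and 2 EZH2 hairpins, 1 library per condition. The table has 5 columns of values, 4 of which name 1 condition each, while the last names the EZH2 knockdown without a hairpin. That column is used as the authors' value for the knockdown. How it was made from the hairpin libraries is not given in the sources used here.

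Depth was approached through the spacing of low values, because FPKM holds no totals. Among genes under 0.5 FPKM in both columns, the ratio to vehicle piled up at 0.949 for GSK126 (273 genes within 0.01 on the log2 scale, against a median of 3 per window), 1.05 for astemizole (256 genes, median 4) and 0.858 for scramble shRNA (274 genes, median 3). These are the relative values of 1 read. For the knockdown column the 2 highest piles were sought, and only in a limited range around 0.5 times vehicle. They lay at 0.454 (111 genes) and 0.540 (60 genes) against a median of 15 per window. Doubled they are 0.908 and 1.08, as a mean over 2 libraries would give. The search set the number of steps and their range beforehand, so it cannot show how this column was made. Sums of FPKM were 795944 for vehicle, 685752 for GSK126, 772398 for astemizole, 661331 for scramble shRNA and 675565 for the knockdown, and 17971, 18414, 17870, 17675 and 18789 names stood above 0. Without totals no counting interval can be given, and a value of 0 may be a failed estimate.

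The table has 28503 lines. Of these, 27 whose names had turned into dates were left out, as were 1635 short non-coding RNA genes. Genes at 1 FPKM or more in at least 1 of the 5 columns were kept, 12934 in all, of which 12142 had a name found in the reference symbol tables. Ratios were computed as log2 of FPKM + 1 in the treated column over FPKM + 1 in its control: GSK126 and astemizole against vehicle, the knockdown against scramble shRNA, and, beside these 3 comparisons, astemizole against GSK126 and scramble shRNA against vehicle. Genes at 2-fold or more were counted. With 1 value per condition no test, p-value or standard deviation is given. Coordinates are not given, because the annotation at hand follows a later build than the authors'.

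Gene lists (30, with 558 members), the comparisons, the rule for named genes and 7 of the alternatives were fixed before the data were examined. A list was described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins, given for lists with 5 or more measured members. A list is said to stand apart at a percentile under 1 or over 99, as a description of these libraries. Named were EZH2, EZH1, EED and SUZ12 in every comparison; the 8 highest and 8 lowest genes of each comparison among those at 5 FPKM or more in at least 1 of the libraries; up to 4 members of each list with the largest ratios; and the 8 highest and 8 lowest shared genes. Because many of these were unresolved names or were listed at 0, the 12 highest and 12 lowest with a known symbol and no 0 were added after their values were seen. Further genes named outside the rule, such as KLK3 and TMPRSS2, and KLK2, TRPM8 or FKBP5 where they are not among the largest, were also chosen after their values were seen. The values of a few genes that this rule or the lists take in, with 1 short list and 1 test that rest on them, are not reported here.

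Comparisons that share the vehicle column were set against 100 simulations of unchanged libraries against that column, and overlaps against the number shared by independent lists. The steps were tested on simulated data for astemizole against vehicle: with 12934 genes of which 50 each were changed 3-fold or 5-fold up or down, 100% were called in each class, and 4 of 12734 unchanged genes (0.0314%) were called. The noise was normal, and changes were put only in genes at 5 FPKM or more with vehicle, on the scale that was scored. This checks the steps and gives no rate of false calls in the real libraries. There, scramble shRNA had 22 genes at least 2-fold higher and 110 lower than vehicle. Of 100 random lists with no effect, 2 stood apart. Those lists held genes with independent noise, unlike lists of genes regulated together, so this is no background rate for the lists used here. Between the 2 control columns several lists also stood apart, G2 and M phase and p53 target genes among them.

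The settings tried besides were a pseudocount of 0.1 FPKM, that pseudocount without a filter on low values, a mean of 1 FPKM or more, 5 FPKM or more in at least 1 column, rescaling to TPM, median-of-ratios scaling, and keeping short non-coding RNA genes. Chosen after seeing the data were 3 more: the other control column, leaving out names listed at 0 in any column, and leaving out liver genes. A first list of liver genes (19 members) and 7 added lists were also written after results had been seen; a second list of liver genes (40 members) was written before its values were looked at. Departures from the plan follow from the single knockdown column: the comparisons of each hairpin became 1 comparison, filters over 6 libraries apply to 5 columns, shared genes of both hairpins could not be counted, and the planned limma fit of both hairpins was not run. Calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.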

Results

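Polyadenylated RNA was sequenced from C4-2 cells, an established prostate cancer line derived from LNCaP. Cells at passages 10 to 15 received vehicle, GSK126, astemizole, lentivirus carrying a scramble shRNA, or lentivirus carrying 1 of 2 EZH2 shRNAs. EZH2 is the methyltransferase subunit of Polycomb repressive complex 2 (PRC2), and EED and SUZ12 are its core partners. GSK126 inhibits the catalytic activity of EZH2, and astemizole is an antihistamine reported to disrupt the binding of EZH2 to EED. The labels list 6 libraries, 1 per condition, and the deposited FPKM table has 5 columns, with the EZH2 knockdown as a single column set by the authors. No condition had a second value, so no difference below has a replicate check, and ratios describe these libraries only. Read totals are not in the table, and absolute depth is therefore unknown. From the spacing of low values, 1 read was worth 0.949 times as much FPKM with GSK126 as with vehicle, 1.05 times with astemizole and 0.858 times with scramble shRNA. The 12934 genes at 1 FPKM or more in at least 1 column were compared as log2 ratios of FPKM + 1, a scale that understates the differences of low genes.

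The targeted gene was examined first in every column. EZH2 stood at 26.5 FPKM with vehicle, 17.5 with GSK126, 9.48 with astemizole, 24.6 with scramble shRNA and 3.35 in the knockdown column. The log2 ratio to the matched control was -2.55 for the knockdown, -1.39 for astemizole and -0.58 for GSK126. EED was at 14.9, 10.6, 7.71, 13.6 and 8.16 FPKM in the same order, giving log2 ratios of -0.46 with GSK126, -0.87 with astemizole and -0.67 with knockdown. SUZ12 gave -0.23, -0.62 and -1.04. EZH1, the second PRC2 methyltransferase, gave 0.19, 0.21 and 0.89.

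**Figure D1:**
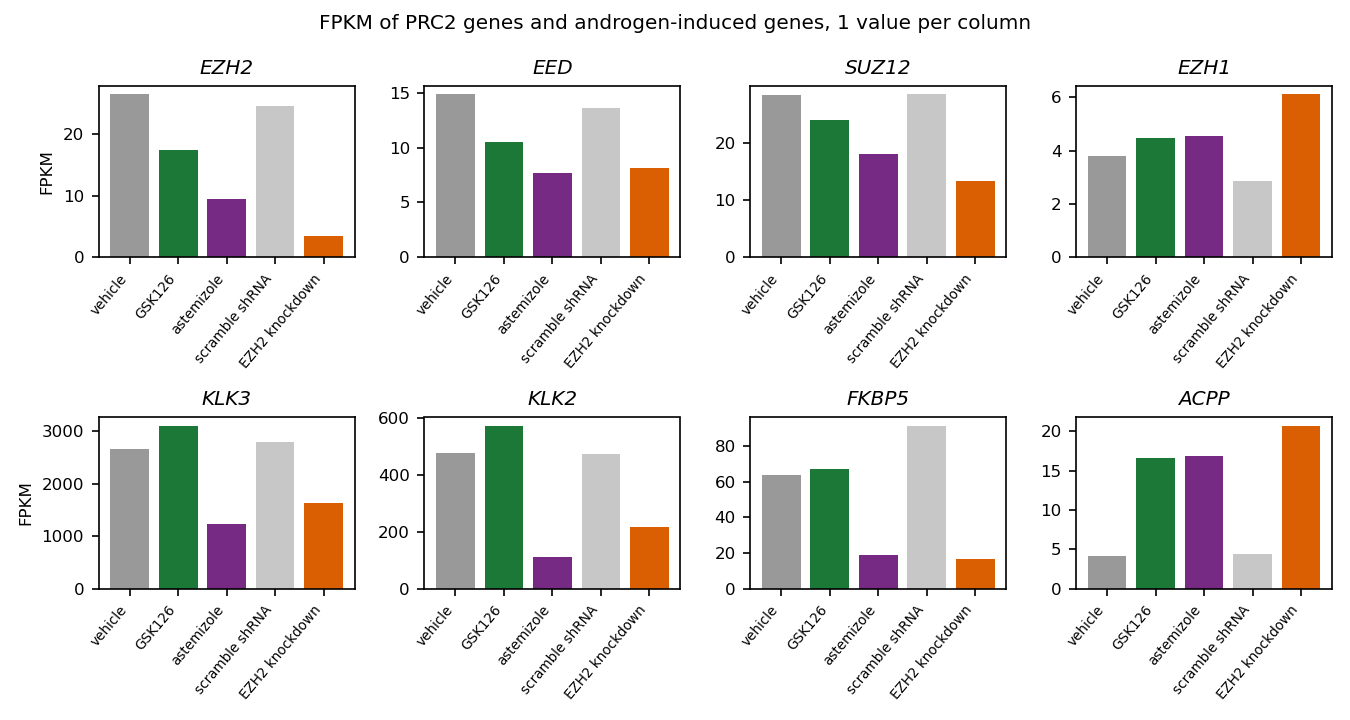
FPKM (y axis, linear from 0) of EZH2, EED, SUZ12, EZH1, KLK3, KLK2, FKBP5 and ACPP in the 5 columns, 1 bar per column and without error bars because each condition has 1 value. EZH2 was lowest in the knockdown column at 3.35 FPKM, and FKBP5 stood at 18.6 FPKM with astemizole and 16.4 in the knockdown column against 64.1 and 91.5 in their controls.

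GSK126 against vehicle addressed which transcripts differ when the catalytic activity of EZH2 is inhibited. Proliferation genes were lower and androgen-induced genes slightly higher in the GSK126 library. Of 23 S phase genes, 9 were at least 2-fold lower and 0 higher, with a median log2 ratio of -0.94; the replication licensing factor CDT1 had -1.16 and the polymerase clamp PCNA -1.13. Of 24 G2 and M phase genes 3 were at least 2-fold lower, with a median of -0.80, led by the mitotic kinase AURKB at -1.26, the ubiquitin-conjugating enzyme UBE2C at -1.07 and CDK1 at -1.06. Both medians lay below all 10000 random lists of the same size and expression. Against the scramble column the G2 and M phase median was -0.35.

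In all, 136 genes were at least 2-fold higher with GSK126 and 123 lower, so 52.5% of these genes were higher. With a pseudocount of 0.1 FPKM the counts were 370 and 236, or 61.1% higher. After TPM rescaling, which moved the median of all genes by 0.19, the counts were 300 and 73, or 80.4% higher. Against the scramble column they were 197 and 51, or 79.4% higher. The 33 measured androgen-induced genes had a median of 0.23, above all matched random lists, with 2 members at least 2-fold higher and 0 lower; after TPM rescaling the median was 0.43. Against the scramble column it was 0.10, and that column itself had a median of 0.11 against vehicle (percentile 100). ACPP, the gene of prostatic acid phosphatase, had a log2 ratio of 1.79, the transcription factor MAF 1.36, RAB3B 0.78 and PMEPA1 0.76. The prostate-specific antigen gene KLK3 had 0.22 and its neighbour KLK2 0.27. Of 5 measured androgen-repressed genes 2 were at least 2-fold higher and 0 lower, with a median of 0.64 (percentile 99.9), CAMK2N1 among them at 1.18. The 14 measured steroid receptor coregulators and pioneer factors had a median of 0.17 (percentile 99.1; 0.38 after TPM rescaling) and no member past 2-fold; the scramble column had 0.21 against vehicle for the same list.

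Among the other lists, 14 measured genes reported as repressed by EZH2 had a median of 0.20 (percentile 96.1), and 2 of them were at least 2-fold higher: the ligand gene WNT5A at 1.52 and the receptor gene BMPR1B at 1.32. The 12 PRC2 genes had a median of -0.25 (percentile 2.60), and no member passed 2-fold. The 18 hypoxia and glycolysis genes had a median of -0.61, below all random lists, with 1 member at least 2-fold lower, the glycolytic regulator PFKFB4 at -1.33. The 20 integrated stress response genes had a median of -0.47, also below all random lists, with no member past 2-fold, and against the scramble column this median was -0.02. The 27 lysosome genes had a median of 0.28 (percentile 100; 0.50 after TPM rescaling), with GPNMB at 1.67 and the peptidase gene TPP1 at 1.12. The 16 ER chaperone genes had a median of 0.04 (percentile 99.9), which was 0.26 after TPM rescaling and 0.31 against the scramble column. Medians of the p53 target genes (-0.13, percentile 30.0), cholesterol synthesis genes (-0.27, percentile 11.2), fatty acid synthesis genes (-0.13, percentile 72.1) and HOX genes (0.10, percentile 68.6) were within the range of random lists with vehicle as the control. The p53 and fatty acid medians turned positive after TPM rescaling, at 0.04 and 0.08. Scramble shRNA itself had p53 and HOX medians of -0.51 and -0.37 against vehicle, so these 2 results may depend on the control.

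The 8 genes with the highest ratios included 6 genes expressed by liver: APOA2 at 3.28, AFP at 2.77, SERPINA1 at 2.57, APOA1 at 2.57, ALB at 2.52, and AHSG, which stood at 13.9 FPKM against 0.866. Albumin (ALB) stood at 28.7 FPKM with GSK126, 4.18 with vehicle and at most 0.133 in each of the other 3 columns. Members of 2 lists of liver genes, 1 written after these values were seen, made up 19 of the 136 genes higher with GSK126, and without them 117 were higher. In the first list, 18 of 19 members (94.7%) were at least 2-fold above the other 3 columns with GSK126, and 16 of 18 (88.9%) were above those columns with vehicle. LYZ, 1 of 2 measured blood cell markers, was at 7.57 FPKM with GSK126 and 1.03 with vehicle.

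Genes that are not in the liver lists and had high ratios were NAALADL2 at 2.74, C11orf92 at 2.36, SERPINI1 at 2.10, the kinase gene PLK2 at 1.81 and TMEFF2 at 1.78. Among the lowest were the core histone gene HIST1H4C at -1.57, the melanocyte lineage factor MITF at -1.61, CBR3 at -1.51, IFITM1 at -1.33, HILPDA at -1.31 and the metallothionein gene MT2A at -1.31. C1orf112 had -5.47 because of the vehicle column, which stood at 290 FPKM while the other 4 columns lay between 2.00 and 7.44. TUBA1A had -2.04 against vehicle and 0.82 against the scramble column. The remaining genes with extreme ratios were mostly clone or accession-like names listed at 0 in at least 1 of the columns, and no fold is given for them here.

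Astemizole against vehicle addressed which transcripts differ when the pairing of EZH2 with EED is targeted. Cell division genes and androgen-induced genes were lower with astemizole, and genes of cholesterol synthesis, the lysosome and the integrated stress response were higher. All 24 G2 and M phase genes were at least 2-fold lower, with a median of -2.82, as were 21 of 23 S phase genes, with a median of -1.69. Among androgen-induced genes 10 of 33 were at least 2-fold lower and 1 higher, with a median of -0.53. These 3 medians lay below all 10000 matched random lists. In all, 456 genes were at least 2-fold higher and 710 lower (39.1% higher), and against the scramble column the counts were 591 and 504 (54.0% higher). With a pseudocount of 0.1 FPKM they were 750 and 1021 against vehicle (42.3% higher).

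The lowest members of the G2 and M phase list were the kinetochore motor CENPE at -3.59, the anaphase activator CDC20 at -3.35, the cyclin gene CCNB2 at -3.23 and the kinase gene PLK1 at -3.23. PTTG1, which encodes securin, had -3.88. In the S phase list the ribonucleotide reductase subunit RRM2 had -2.90, GINS1 -2.29 and UHRF1 -2.26. Of the androgen-induced genes, KLK2 was at 111 FPKM against 477 (-2.10), FKBP5 at 18.6 against 64.1 (-1.73) and KLK3 at 1230 against 2675 (-1.12). NCAPD3 had -1.39 and TMPRSS2 -0.49. ACPP went the other way, at 16.9 FPKM against 4.09 (1.81). KLK3 and TMPRSS2 are list members named here after their values were seen. The 5 androgen-repressed genes had a median of 1.03 (percentile 99.9) with 3 at least 2-fold higher, CAMK2N1 at 1.39 among them and FOLH1, which encodes prostate-specific membrane antigen, just below at 0.98. That median was 0 when low genes were kept with a smaller pseudocount.

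Of 23 cholesterol synthesis genes 11 were at least 2-fold higher and 0 lower, with a median of 0.88, including the sterol reductase TM7SF2 at 2.22, HMGCS1 at 1.69, STARD4 at 1.55 and SC5D, at 77.9 FPKM against 26.8. Among 27 lysosome genes 10 were higher and 0 lower, with a median of 0.81. GPNMB had the highest ratio of this list, at 148 FPKM against 5.75 (4.46), followed by the sialidase gene NEU1 at 2.13, TPP1 at 1.90 and the autophagy receptor gene SQSTM1 at 1.81. The 20 integrated stress response genes had 10 members at least 2-fold higher and 0 lower, with a median of 1.01: the cystine transporter gene SLC7A11 at 1.91, asparagine synthetase ASNS at 1.68, CHAC1 at 1.60 and DDIT3, which encodes CHOP, at 85.6 FPKM against 29.5. Antigen presentation genes had a median of 0.80 over 13 members, 2 of them at least 2-fold higher, TAPBP at 1.17 and HLA-B at 1.12. Each of these 4 medians lay above all matched random lists.

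The 21 p53 target genes had a median of 0.45 (percentile 100) with 4 members at least 2-fold higher, CDKN1A at 1.90, BBC3 at 1.60, TP53INP1 at 1.45 and GADD45A at 40.6 FPKM against 15.9; against the scramble column the median was 0.77. The 18 hypoxia and glycolysis genes had a median of -0.98 with 9 members at least 2-fold lower, led by the lactate dehydrogenase gene LDHA at -2.39, PFKFB3 at -1.72 and PFKFB4 at -1.53. The 12 PRC2 genes had a median of -0.61 (percentile 0.0600). The 14 genes reported as repressed by EZH2 had a median of 0.13 (percentile 85.9) with 2 higher and 1 lower; the cyclin-dependent kinase inhibitor gene CDKN2B stood at 10.5 FPKM against 0.282 (3.17) and IGFBP3 at 2.26. In the HOX list HOXB9 had 2.14 while the median was -0.00. Of 14 fatty acid synthesis genes 3 were at least 2-fold higher, among them the desaturase gene SCD at 1.98. ER chaperone genes had a median of -0.43 (percentile 2.71), with MANF at -1.38 and HSP90B1 at -1.18.

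Outside the lists, high ratios belonged to LCN2, which encodes an iron-trafficking lipocalin, at 3.54, the trypsinogen gene PRSS1 at 3.52, the heat shock gene HSPA6 at 3.35, the deiodinase gene DIO3 at 3.31 and S100P at 3.26. The xenobiotic enzyme gene CYP1A2 had 2.83, NOS3 2.60 and ID2 2.56. Low ratios belonged, besides PTTG1, to PHGR1 at -4.17, the neuropeptide gene NMU at -4.07, the gastric protease gene PGC at -3.82 and TM4SF1 at -3.57. C1orf112 had -6.09, again because of the vehicle column.

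The knockdown column against scramble shRNA addressed which transcripts differ when EZH2 itself is depleted. Cell division genes were lower and p53 target genes higher, and androgen-induced genes were again lower. All 24 G2 and M phase genes and 22 of 23 S phase genes were at least 2-fold lower, with medians of -3.29 and -2.53. Of 21 p53 target genes 12 were at least 2-fold higher and 0 lower, with a median of 1.12. Among 33 androgen-induced genes 7 were at least 2-fold lower and 2 higher, with a median of -0.56. In all, 251 genes were at least 2-fold higher and 661 lower (27.5% higher), and with a pseudocount of 0.1 FPKM 490 and 1004 (32.8% higher). With vehicle as the control the p53 median was 0.72 and the androgen-induced median -0.29.

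In the G2 and M phase list CENPE had -4.14, CDC20 -3.80, TOP2A -3.73 and NUSAP1 -3.72. S phase genes at the low end were RRM2 at -3.95, the helicase subunit CDC45 at -3.73 and the licensing factor CDC6 at -3.63. Outside the lists, the transcription factor MYBL2 had -4.14, the histone chaperone ASF1B -4.08 and thymidine kinase TK1 -3.86. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, was at 370 FPKM against 48.0 (2.92), SESN1 had 2.17, BTG2 2.12 and MDM2, whose product degrades p53, 1.93. Among androgen-induced genes FKBP5 had -2.41, CAMKK2 -1.32, NCAPD3 -1.29 and KLK2 -1.11, KLK3 had -0.77, and ACPP was higher at 20.7 FPKM against 4.40 (2.01). The cation channel gene TRPM8 had 1.22.

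The 18 hypoxia and glycolysis genes had a median of -0.81 with 8 at least 2-fold lower, among them PFKFB3 at -1.85, BNIP3 at -1.73, PDK1 at -1.61 and LDHA at -1.51. Lysosome genes had a median of 0.46 (percentile 100) with 2 members higher. The 12 PRC2 genes had a median of -0.50 (percentile 0.180), with 4 at least 2-fold lower and 1, JARID2, higher at 1.10; PHF19 had -1.25. Integrated stress response genes had a median of -0.29 (percentile 0.230) and ER chaperone genes one of -0.36 (percentile 0.150), and these were -0.77 and -0.60 with vehicle as the control. The 5 mesenchymal markers had a median of 0.55 (percentile 99.1) and no member past 2-fold; the median was 0.12 when low genes were kept with a smaller pseudocount. Genes reported as repressed by EZH2 had a median of -0.02 (percentile 41.2). Of 14 measured, 3 were at least 2-fold higher, IGFBP3 at 1.56, WNT5A at 1.44 and CDKN2B at 1.10, and 1 was at least 2-fold lower. HOX genes had 0.17 (percentile 89.1), with HOXC13 at 1.61 and HOXC6 at 1.07. Of 4 measured neuroendocrine markers, SYP was at 4.63 FPKM against 0.510 and SCG3 at 3.45 against 0.0335, while ENO2 had -1.02. Cholesterol synthesis genes had a median of 0.01 (percentile 35.1), and the desaturase genes FADS2 and FADS1 had -1.82 and -1.58.

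The highest ratios included ID3 at 2.96 and ID1 at 2.86, which encode inhibitors of basic helix-loop-helix factors, TARP at 2.59, TNFSF15 at 2.49, SCGB1D2 at 2.47, the matrix glycoprotein gene THBS1 at 2.36 and FAM198B at 2.34. The knockdown column listed 8 names at 0 that stood at 5 FPKM or more in all other columns, among them the mitochondrial names cytochrome b and MTND5. These 8 names were the lowest in this comparison, and no fold is given for them.

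**Figure D2:**
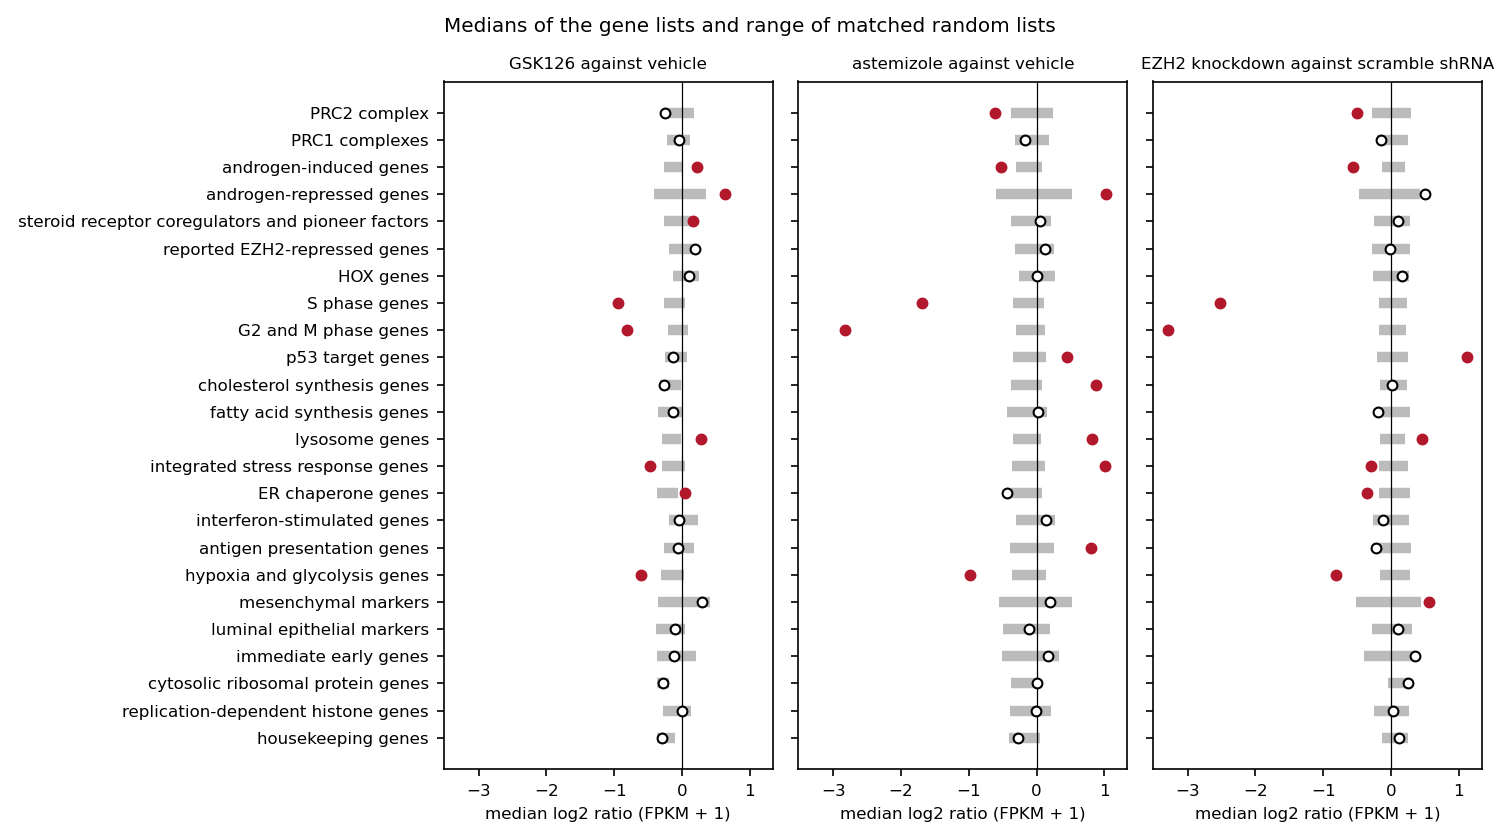
Median log2 ratio of FPKM + 1 (x axis) of the gene lists with at least 5 measured members (y axis) in the 3 comparisons, where grey bars span the central 95% of 10000 matched random lists and red points have a percentile under 1 or over 99. G2 and M phase genes lay at -0.80 with GSK126, -2.82 with astemizole and -3.29 with knockdown, and androgen-induced genes at 0.23, -0.53 and -0.56.

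The lists not named so far gave small medians or had few members. With GSK126, astemizole and knockdown in turn, PRC1 genes had medians of -0.04, -0.17 and -0.15, interferon-stimulated genes -0.05, 0.14 and -0.12, luminal epithelial markers -0.11, -0.11 and 0.10, immediate early genes -0.12, 0.17 and 0.36, ribosomal protein genes -0.28, 0.01 and 0.25, histone genes -0.00, -0.01 and 0.03, and housekeeping genes -0.29, -0.27 and 0.12. No percentile of these lay under 1 or over 99, and several of these signs changed with the control or the scaling. Basal markers (3 measured), fibroblast markers (1) and blood cell markers (2) had too few members for a percentile. Their medians were -0.25, -0.48 and -0.50 for the basal markers, -0.22, 0.22 and 0.58 for the fibroblast marker, and 0.89, -0.24 and -0.12 for the blood cell markers. None of the 13 mitochondrially encoded genes was found under its standard symbol.

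The overlap between comparisons was examined next, to ask whether targeting EZH2 in different ways gives the same genes. Astemizole and knockdown, which have separate controls, shared 399 genes at least 2-fold lower, where independent lists of these sizes would share 36.3, and 62 higher, where 8.85 would be shared. The shared lower genes included CENPE, NMU, CDC20, CCNB2, PLK1, PTTG1, HMMR and PBK. Among the 399 were 75 members of 3 cell cycle gene lists, 1 of them added later. They were 45 of 47 measured members of the fixed lists and 30 of 32 of the added list. PTTG1 is in none of these lists, so 75 is not a count of all cell division genes among the 399. The shared higher genes included ID1, ID3, GPNMB, FGF13, CDKN1A, ACPP and RNF144B. Genes past 2-fold in opposite directions numbered 10 higher and 11 lower with astemizole, against 23.3 and 13.8 for independent lists. Across genes, which are not independent replicates, the correlation of the log2 ratios was r = 0.45 (Spearman rho 0.38). Without names listed at 0 in any column r was 0.56.

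GSK126 and knockdown shared 31 higher genes (2.64 if independent, and 53 after TPM rescaling), including C11orf92, NAALADL2, ACPP, TMEFF2 and WNT5A. They shared 68 lower genes (6.29 if independent), a number that was 24 after TPM rescaling and 30 against the other control. Across genes r was 0.29 and rho 0.31, and r was 0.40 without names listed at 0 in any column. GSK126 and astemizole shared 40 higher genes (4.79 if independent), including BACE2, PKIB and GPNMB, and 94 lower genes (6.75 if independent), with r = 0.57 and rho 0.62. After TPM rescaling these counts were 96 and 51, and against the other control 75 and 34. These 2 compounds share the vehicle column, and unchanged libraries simulated against that column gave r = 0.50, with 0.03 higher and 0.05 lower genes shared. That r follows from sharing a column with equal noise, so it describes the simulation and not these libraries. The covariance was 0.154 against 0.0338 in the simulation, a difference of 0.120, and part of the excess overlap may come from the shared column. The simulated noise was normal, and its spread took little account of outlying genes. Both 0.0338 and the simulated counts may therefore understate what the shared column adds. The 8 shared lower genes taken by the naming rule, C1orf112 and TUBA1A among them, were also lower with scramble shRNA than with vehicle. These 2 had log2 ratios of -5.11 and -2.85 there. With a separate control for each compound r was 0.31 or 0.33, and the covariance was 0.0811 or 0.0807. In all 3 comparisons, 15 genes were at least 2-fold higher (0.0930 if independent; 30 after TPM rescaling and 51 with a pseudocount of 0.1 FPKM), including ACPP, GPNMB, BACE2, FAM198B, SIDT2, CAMK2N1, GRIN3A and ENC1. The 61 genes lower in all 3 (0.345 if independent) included HIST1H4C, PFKFB4, IFITM1, RPRML, AURKB, TK1 and CKS1B, and their number was 20 after TPM rescaling, 24 against the other control, 39 with median-of-ratios scaling and 107 with that pseudocount.

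**Figure D3:**
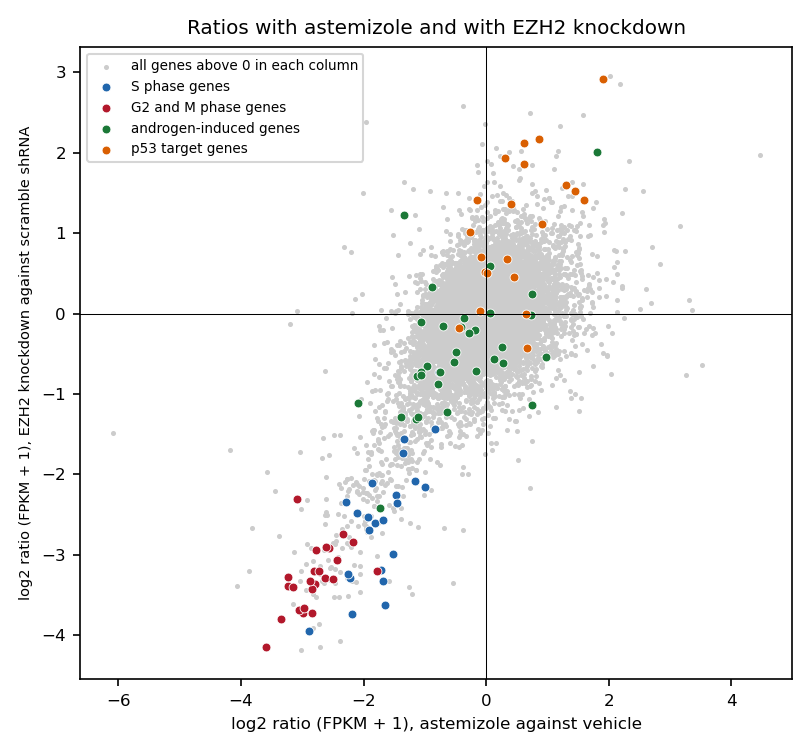
Log2 ratios of FPKM + 1 with astemizole against vehicle (x axis) and with EZH2 knockdown against scramble shRNA (y axis), 1 point per gene above 0 in each column, with members of 4 gene lists coloured. G2 and M phase genes sit at the lower left, with CENPE at -3.59 and -4.14, and CDKN1A, a p53 target, at 1.90 and 2.92.

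The compounds were also set against each other directly, although their doses and times are not in the labels. Relative to GSK126, the astemizole library had 283 genes at least 2-fold higher and 424 lower. Androgen-induced genes had a median of -0.68 with 10 of 33 at least 2-fold lower and 0 higher, including KLK2 at -2.36, FKBP5 at -1.80, TRPM8 at -1.77 and SLC45A3 at -1.61. All 24 G2 and M phase genes were at least 2-fold lower (median -1.98). Of 23 cholesterol synthesis genes 19 were at least 2-fold higher (median 1.34), as were 16 of 20 integrated stress response genes (median 1.36). Genes with high ratios were PRSS1 (4.25), LCN2 (3.57), HSPA6 (3.53), S100P (3.44) and ID1 (3.31), and the ferritin heavy chain gene FTH1 had 2.29. Genes with low ratios included the liver genes APOA2, ALB and AFP, PHGR1 at -4.36 and PGC at -4.10.

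**Figure D4:**
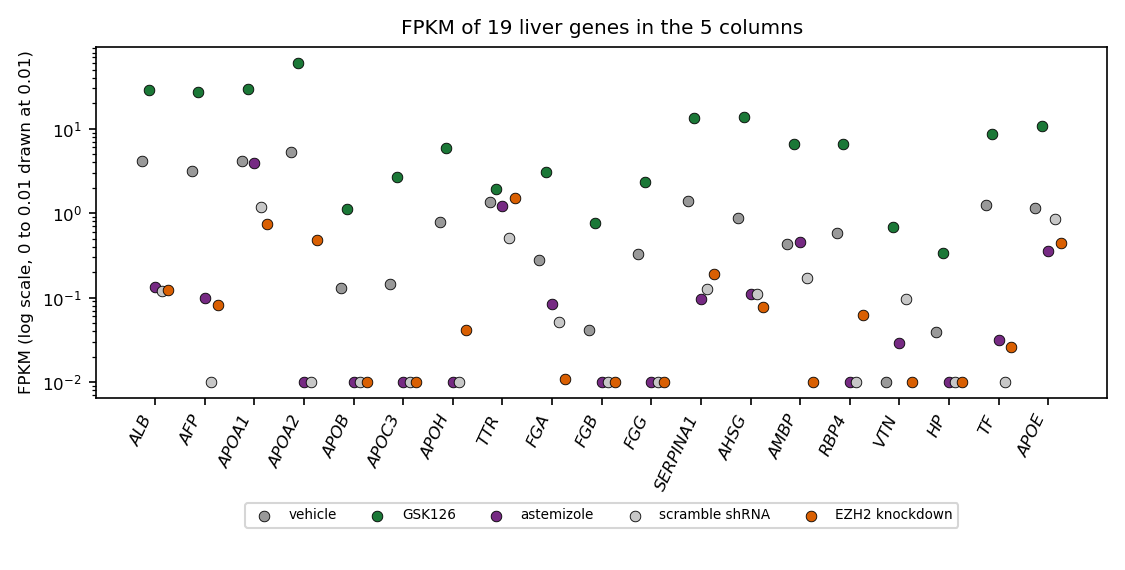
FPKM (y axis, log scale, values under 0.01 drawn at 0.01) of the 19 genes of the first liver list in the 5 columns, 1 point per column. ALB stood at 28.7 FPKM with GSK126 and 4.18 with vehicle, and at 0.133 or less in the other 3 columns.

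The 2 control columns were compared to show how far libraries without EZH2 depletion or inhibition lay apart; they also differ by lentiviral infection. Scramble shRNA had 22 genes at least 2-fold higher and 110 lower than vehicle. The p53 target list had a median of -0.51, with CDKN1A at -1.03, and the G2 and M phase list one of -0.51, both below all matched random lists. HOX genes had a median of -0.37 (percentile 0.0400), histone genes -0.37 (percentile 0.370) and integrated stress response genes -0.34 (percentile 0.580). Androgen-induced genes (0.11), steroid receptor coregulators (0.21) and hypoxia and glycolysis genes (0.19) had medians at percentile 100, cholesterol synthesis genes one of -0.03 at percentile 99.5 and fatty acid synthesis genes one of 0.04 at percentile 99.8.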

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

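The test of an unusual vehicle library in this part was chosen only after the result was seen.

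Androgen-induced genes had medians of opposite sign in groups that target the same protein, 0.23 with GSK126, -0.53 with astemizole and -0.56 with EZH2 knockdown (-0.29 with vehicle as its control), a difference that was not tested because each condition has 1 value. An unusual vehicle library as the whole cause of a fall with astemizole and none with GSK126 is argued against. With scramble shRNA as the control the median was -0.68 with astemizole and 0.10 with GSK126. That 0.10 lies near the median of all genes in the same comparison, 0.05, so a rise with GSK126 is not settled by this exchange. Fewer dividing cells as an explanation stays open, since 0 androgen-induced members belong to the cell cycle lists and leaving such members out moved nothing, with the higher of both medians at -0.53. A different effect of blocking the enzyme and of removing or unpairing the protein stays open as a possible biological explanation and was not tested. Astemizole and knockdown both had lower cell cycle genes but differed in other lists, such as cholesterol synthesis (medians 0.88 and 0.01). The dose and time of astemizole are not in the labels. The fall with astemizole therefore cannot be assigned to EZH2 from these values.

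Integrated stress response genes also had medians of opposite sign, -0.47 with GSK126 (-0.02 against the other control), 1.01 with astemizole and -0.29 with EZH2 knockdown, and the difference was not tested. ER chaperone genes had 0.04 with GSK126 and -0.36 with EZH2 knockdown, standing apart from random lists in opposite directions, and the difference was not tested.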

How the results depend on the processing

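The other control column, leaving out names listed at 0 and leaving out liver genes were chosen only after the results were seen; the other 7 alternatives were planned. Over 517 results, a count is called moved when it differs by over 1.5 times, a correlation by over 0.1, a list median by over 0.195, and a gene by over 1 robust SD between the control columns at its expression. Of counts, 41 values moved and 99 did not, of correlations 4 and 26, of list medians 72 and 636, and of genes 561 and 3597, with 4 genes reversed. The knockdown rests on the authors' single column, so the planned limma fit was not run, and leaving out a replicate does not apply to groups of 1. No paired analysis was possible because each condition has 1 value. Depth limits low genes most: total reads are unknown, and the smaller pseudocount, which gives low genes more weight by construction, moved most of the counts.

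With a pseudocount of 0.1 FPKM, genes past 2-fold numbered 370 higher and 236 lower with GSK126, 750 higher with astemizole, and 490 higher and 1004 lower with knockdown. Shared genes numbered 172 higher and 162 lower for GSK126 and astemizole, 93 and 124 for GSK126 and knockdown, 131 higher for astemizole and knockdown, and 51 and 107 for all 3. EZH2 in the knockdown column had -2.84. Medians were 1.06 with GSK126 and 1.44 with astemizole for androgen-repressed genes, and with knockdown -2.74 for S phase and -3.71 for G2 and M phase genes. All genes counted in these comparisons before were among those counted here, which follows by construction because a smaller pseudocount can only widen a ratio.

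Without a filter and with that pseudocount, which adds low genes by construction, the numbers were 979 and 517 with GSK126, 1344 and 1534 with astemizole, and 880 and 1384 with knockdown. Shared genes were 346 and 313 for the compounds, 158 and 164 for GSK126 and knockdown, 208 and 634 for astemizole and knockdown, and 86 and 133 for all 3. Correlations with the knockdown were 0.18 for GSK126 and 0.32 for astemizole. EZH2 again had -2.84, S phase genes -2.74 and G2 and M phase genes -3.71 with knockdown. The medians of androgen-repressed genes with astemizole, 0, and of mesenchymal markers with knockdown, 0.12, include more low members.

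At 5 FPKM or more in at least 1 column, which tests fewer genes, 83 genes were higher with GSK126. With a mean of 1 FPKM or more, the antigen presentation median with astemizole was 0.59; the cause was not tested. Leaving out names listed at 0 in any column gave correlations with the knockdown of 0.40 for GSK126 and 0.56 for astemizole, by removing the names set at 0. Without the liver genes 117 genes were higher with GSK126, and no count, correlation or list median moved by more than its tolerance.

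TPM rescaling moved the median GSK126 ratio of all genes up by 0.19, since the sum of FPKM was lower in that column. It gave 300 genes higher and 73 lower with GSK126, 96 and 51 shared with astemizole, 53 and 24 shared with knockdown, and 30 and 20 in all 3. Of the 123 lower genes 66 remained. Medians with GSK126 were 0.43 for androgen-induced, 0.85 for androgen-repressed, 0.38 for steroid receptor coregulator, -0.73 for S phase, -0.60 for G2 and M phase, 0.50 for lysosome, -0.27 for integrated stress response, 0.26 for ER chaperone and -0.41 for hypoxia and glycolysis genes. With median-of-ratios scaling, 39 genes were lower in all 3; the cause was not tested.

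Against the other control column, 51 genes were lower with GSK126, of which 19 were among the 123 lower against vehicle. Shared genes were 75 higher and 34 lower for the compounds, 30 lower for GSK126 and knockdown, and 24 lower in all 3. With GSK126 the medians were -0.35 for G2 and M phase, -0.02 for integrated stress response, 0.31 for ER chaperone and -0.84 for hypoxia and glycolysis genes. With astemizole they were -2.35 for G2 and M phase, 0.77 for p53 target, 1.10 for cholesterol synthesis, 1.41 for integrated stress response and -1.19 for hypoxia and glycolysis genes. With knockdown they were -0.29 for androgen-induced, -3.83 for G2 and M phase, 0.72 for p53 target, -0.77 for integrated stress response and -0.60 for ER chaperone genes. Direction turned for LINC00035 (-0.05) and TUBA1A (0.82) with GSK126. It also turned for AK024535 (0.52) with GSK126 and BC034020 (-0.75) with knockdown, but the scramble column lists both at 0, so their ratios against it rest on the pseudocount and are not read as folds. These values move because the controls themselves differ, and the cause of that difference was not tested.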

Other observations

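The added gene lists in this part, the first liver list, and the tests of EZH2 derepression, induction by GSK126 alone in either library, scaling and an unusual control library were chosen only after the results were seen.

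Genes outside the fixed lists showed further differences with astemizole. Of 14 measured targets of the oxidative stress factor NRF2, 6 were at least 2-fold higher and 0 lower, with a median of 0.94, against -0.13 with GSK126 and 0.04 with knockdown. FTH1 and SLC7A11 had been seen before this list was written; the other 12 had a median of 0.86 with astemizole, from 0.03 to 1.84, with 4 at least 2-fold higher. The iron storage genes FTH1 and FTL stood at 9758 and 1363 FPKM with astemizole against 2104 and 381 with vehicle, and HMOX1, which encodes heme oxygenase, at 59.5 against 17.1. SLC7A11 is also a member of the integrated stress response list. Autophagy genes had a median of 0.12 (percentile 92.3) with 2 of 16 at least 2-fold higher, GABARAPL1 at 1.69 and MAP1LC3B at 1.13, and medians of 0.03 with GSK126 and 0.20 with knockdown. Heat shock genes had a median of -0.45 with astemizole, -0.35 with GSK126 and 0.09 with knockdown, although HSPA6, seen before the list was written, had 3.35 with astemizole. Aryl hydrocarbon receptor targets had medians of 0.28, 0.63 and 0.12 with GSK126, astemizole and knockdown, over 5 measured genes that include CYP1A2, also seen before.

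Targets of TGF-beta and BMP signalling had a median of 0.90 over 10 genes with knockdown, 0.32 with astemizole and -0.02 with GSK126. The 4 members at least 2-fold higher with knockdown, ID1, ID2, ID3 and THBS1, had been seen before the list was written; the other 6 had a median of 0.45, from -0.69 to 0.90, and 0.06 with astemizole. ID1 was at 36.9 FPKM in the knockdown column against 4.22 with scramble shRNA, and ID3 at 31.2 against 3.15. Their log2 ratios with astemizole were 2.19 and 2.02, and with GSK126 -1.13 and -0.83. Scramble shRNA itself had -1.20 and -1.04 against vehicle. With GSK126 the 2 genes stood at 4.49 and 3.78 FPKM, slightly above scramble shRNA, so they were lower with GSK126 only against vehicle. The same list was lower with scramble shRNA than with vehicle, at -0.32, and at -0.14 over those 6 members. Metallothionein genes had a median of -1.07 with knockdown, -0.32 with GSK126 and -0.11 with astemizole over 6 genes that include MT2A, seen before, and the control columns themselves differed by 0.82.

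Liver-type transcripts stood out in the GSK126 library and, at a lower level, in the vehicle library. Derepression by loss of EZH2 was not seen in the knockdown column, where the first list had a median log2 ratio of 0. Genes reported as repressed by EZH2 also had a median of only -0.02 there. The knockdown column therefore cannot decide whether inhibiting the enzyme with GSK126 derepressed the liver genes. RNA from liver-type cells, or from another library mixed in, is a candidate source: in a second list whose values had not been looked at, 60% of the 35 members above 0 were at least 2-fold above the other 3 columns with GSK126. Only 14 of its 40 members reached 1 FPKM with GSK126, and its median log2 ratio against vehicle was 0.13. Part of the 60% rests on values near 0, such as C4BPA at 0.0749 FPKM. No such share was taken for other low genes. Induction by GSK126 alone is argued against for the vehicle library, which received none: 25 of the 39 raised members of both lists were at least 2-fold above the other columns without GSK126 there, against at most 2 in any of those columns (25 and at most 4 over all 59 members). For the level in the GSK126 library it cannot be told apart from a mixed-in source, because the share of raised members above the other 3 columns with vehicle, 74.4%, lay between the bounds of a test first set on the second list (59.4% of its 32 members above 0 with vehicle, also undecided) and set again after that value was seen. The source is not identified, and some genes abundant in liver were low in the GSK126 library, with TTR at 1.91 FPKM against 1.36 with vehicle, FGB at 0.759 and HP at 0.338.

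Cell cycle genes were lower with both astemizole and knockdown, the pattern with the most genes among those weighed here. Scaling of whole libraries as the whole cause is argued against by the median of all genes, -0.06 with astemizole and 0.03 with knockdown. Median-of-ratios scaling moved these medians by only 0.08 and -0.03, and left the G2 and M phase medians at -2.74 and -3.33. An unusual control library is argued against by the exchange of controls, which left -2.35 with astemizole and -3.83 with knockdown. In a second list of 32 cell cycle genes not looked at before, 93.8% (30 genes) were at least 2-fold lower in both comparisons. Its medians were -0.82, -2.22 and -2.76 for GSK126, astemizole and knockdown. This met the prediction for fewer dividing cells. As 45 of 47 members of the fixed lists were already lower in both, the second list repeats the pattern and does not set this explanation apart. These values hold no measure of cell number, so lower transcription of the same genes in cells that still divide, for instance through loss of EZH2 itself, stays open and was not tested.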
